A study of Homo sapiens with 2 samples.

How the data were processed

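A549 lung adenocarcinoma cells carrying a red fluorescent reporter of vimentin were profiled by targeted RNA sequencing. Per the labels, 1 library came from cells in which epithelial to mesenchymal transition (EMT) had been induced with transforming growth factor beta (TGF-beta), and 1 library came from cells given no treatment. There were therefore 2 groups with 1 library each. The dose of TGF-beta and the duration of the treatment are not given in the sources used here. Per the labels' protocols, RNA was purified on Qiagen columns and 10 ng of total RNA per library entered the AmpliSeq Transcriptome kit, which amplifies a short segment of each targeted gene by multiplex PCR before sequencing.

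The deposited table held expected counts (estimated counts that need not be whole) for 57736 genes, not normalized, together with 196317 transcript entries and 1195371 exon entries. Of the gene values above 0, 53.1% in the TGF-beta library and 45.3% in the untreated library were whole numbers within a tolerance of 1e-06. The transcript entries held shares within a gene and the exon entries held the gene's count divided over exons, so the gene entries alone were used as counts and the exon entries alone to see how the counts lay along a gene. Coordinates in the deposited table are those of the hg19 build. The submitters' processing notes name hg19 and DESeq without a role or version. The aligner, the counting program and its treatment of strand are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. A human annotation of a later build was used for gene names alone. The positions of the kit's amplicons were not used here.

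The expected counts were rounded to whole numbers, which gave 597133 counts in the TGF-beta library and 674784 in the untreated library. Libraries were scaled with the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 0.946 and 1.06 for the TGF-beta and untreated libraries, and values are given as CPM of the scaled totals. A gene entered the comparison with at least 5 CPM in 1 of the 2 libraries. Its log2 ratio is the TGF-beta library over the untreated library without a pseudocount. A count of 0 was replaced by a floor of 3 counts in that library. The ratio is then a bound set by the floor, and the exact interval can reach nearer to equality. Tallies, over all genes and within lists, and list medians took such bounds at their floor value, and counts of 1 or 2 were kept as they were. A gene with 0 counts in a library can therefore be given a smaller difference than a gene with 1 or 2 counts there. No ratio is given for a gene where both counts were at or under the floor. Such genes pass the filter with 3 counts in the TGF-beta library, and the tallies and list medians hold them at the value the same rule gives. For 3 counts against 0 that value is a log2 ratio of 0.34, which scaling also gives any gene with equal counts. List medians of 0.34 rest at this value. The floor equals 5.31 CPM in the TGF-beta library and 4.21 CPM in the untreated library. Intervals of ratios are exact 95% Clopper-Pearson intervals conditional on the summed count, and intervals of CPM values are exact 95% Poisson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

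With 1 library per group no test of the treatment is possible, no p-value is given, and no difference has a replicate check. Genes were counted by a size rule, at least 2-fold higher or lower. There were 39 gene lists, with 1213 of their 1215 members found among the deposited symbols or their older forms (CD24 and PECAM1 were not matched). For each list the median log2 ratio of its expressed members was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below the 2.5th or above the 97.5th percentile, which describes these 2 libraries and is not a test of the treatment. Of 39 lists of randomly drawn genes, 1.95 would stand apart by chance. Some lists share members, and the members of a list need not vary independently, so this number is not a bound for these lists.

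Genes were named by a rule. It took a panel of 13 EMT and TGF-beta response genes, then the 12 genes with the largest and the 12 with the smallest ratio among genes with at least 20 CPM in 1 of the libraries. It also took up to 4 members of each list that stands apart, those with the largest differences in the direction of the list's median. Members that went the other way in these lists were not taken. Of each other list it took up to 2, those with the largest differences of at least 2-fold in either direction. This gave 141 genes, of which the text names those needed to describe a group, and some are not reported here. Groups, gene lists, size rule, filter, naming rule and a set of alternatives were fixed before the data were examined. Those alternatives were DESeq2 1.42.0 size factors, total counts and upper quartile in place of TMM, other filters on low counts, thinning of the deeper library, log2(CPM + 1), other size rules, a rule on the counting interval, 10 expression bins, and the mean in place of the median. Scaling on ribosomal protein genes, totals without the 20 genes with the most counts, and restriction to genes with at least 10% of their counts outside their main exon or with more than 3 counts in 1 library were added after the data had been seen. No library or gene entry was left out, and 0 other sample columns were present.

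The procedure was tested on simulated counts drawn from the means and library sizes of these libraries, with 200 changed genes. The changed genes were drawn from those with a pooled mean of at least 20 CPM. A difference of 2-fold lies at the cut itself, so the share of such genes that pass does not measure depth. Of 50 genes at each setting, 52.0% of those made 2-fold higher and 46.0% of those made 2-fold lower passed the size rule, as did 98.0% of those made 4-fold higher and 98.0% of those made 4-fold lower. Among 14671 unchanged genes, counting noise alone put 1809 past 2-fold higher and 1468 past 2-fold lower. With a filter of 20 CPM the numbers were 162 and 128 of 4504. Of 100 simulated lists of randomly drawn genes without an effect 3.0% stood apart. With the finished medians of the same 100 lists shifted 2-fold lower, 100.0% stood apart below. Lower members were not simulated, so their counting noise and losses to the filter did not enter. Intervals held the true ratio in 97.0% of 3772 unchanged genes. Calculations were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The DESeq2 size factors, once applied, left 14067 genes past the filter in place of 15401, as genes with 3 counts or fewer in both libraries no longer passed.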

Results

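Gene expression was compared between A549 cells in which TGF-beta had induced EMT and untreated A549 cells. A549 is a lung adenocarcinoma line of epithelial origin, and the cells carried a red fluorescent reporter of vimentin, an intermediate filament protein of mesenchymal cells. The data were 1 AmpliSeq library per condition, and the TGF-beta library is the one labelled as TGF-beta-induced EMT. The TGF-beta library held 595124 expected counts over 22807 genes with a value above 0, and the untreated library held 673135 over 23703 genes. The counts were concentrated in few genes, with 43.7% of the TGF-beta library and 32.7% of the untreated library in the 10 genes with the most counts. Only 1965 genes had at least 20 counts in the TGF-beta library and 3157 in the untreated library. Depth therefore limits most genes to large differences.

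The comparison asks which genes differ between the TGF-beta-induced EMT state and the untreated state. Mesenchymal and EMT marker genes were not higher as a group in the library labelled TGF-beta, with a median log2 ratio of -0.28 over 22 expressed members. Of these, 7 were at least 2-fold lower and 2 at least 2-fold higher, COL1A1 among the latter. Vimentin (VIM) was 6.40-fold lower in that library, and the TGF-beta target gene TGFBI, which encodes a secreted matrix protein, was 21.5-fold lower. Housekeeping genes were lower too, with GAPDH 19.0-fold lower and the 53 expressed ribosomal protein genes 10.5-fold lower at their median. The epithelial cadherin gene CDH1 and the mesenchymal cadherin gene CDH2 had too few counts to tell a difference. These differences have no replicate check.

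The panel genes were read at very different depths. VIM (hg19 chromosome 10, 17270258 to 17279592, plus strand) had 56 counts in the TGF-beta library and 452 in the untreated library, which correspond to 99.1 and 634 CPM and a log2 ratio of -2.68 (95% counting interval -3.10 to -2.27). TGFBI had 15 and 407 counts, with a log2 ratio of -4.43 (-5.28 to -3.69). SMAD7, the inhibitory SMAD of the pathway's feedback loop, had 5 and 22 counts, and its log2 ratio was -1.80 (-3.56 to -0.37). SNAI2, a repressor of epithelial genes, had 0 counts in the TGF-beta library against 11 in the untreated library. With the 0 set to the floor of 3 counts SNAI2 was 2.91-fold lower, and its counting interval reached up to a log2 ratio of -0.99.

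The remaining panel genes were within counting error. SNAI1 had 11 counts in the TGF-beta library and 25 in the untreated library, as did CDH2 (chromosome 18), and both had a log2 ratio of -0.85 (-2.02 to 0.23). CDH1 (chromosome 16, 68771128 to 68869451, plus strand) had 4 counts against 1, with a log2 ratio of 2.34 and an interval from -1.0 to 7.96. EPCAM, an epithelial adhesion gene, had 7 against 4, with a log2 ratio of 1.14 (-0.83 to 3.36). TWIST1 had 4 against 3, and ZEB2 had 5 against 4. FN1, which encodes fibronectin, had 3 against 0, and ZEB1 had 2 against 3, so that neither gave a ratio. A difference in these genes was not detectable at this depth.

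**Figure D1:**
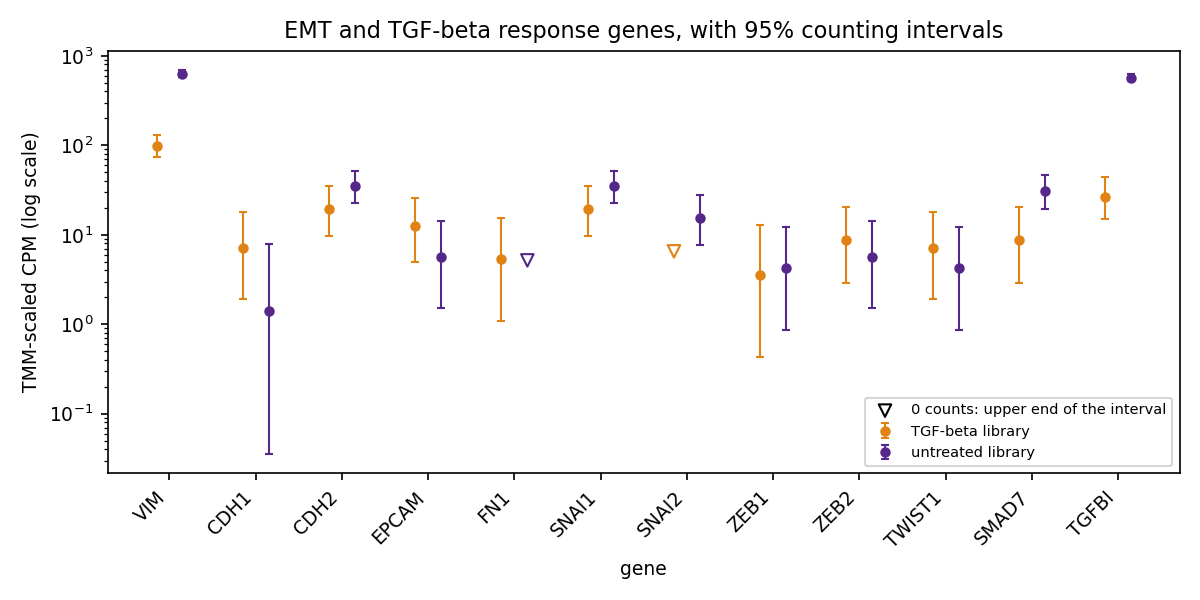
TMM-scaled CPM on a log axis of 12 panel genes in the TGF-beta library and the untreated library, 1 library each, with exact 95% Poisson intervals for counting error only and open triangles at the upper end of the interval where the count was 0. VIM and TGFBI lie lower in the TGF-beta library with intervals that do not overlap.

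Over all genes, 15401 passed the filter on low counts. Of these, 3391 were at least 2-fold higher in the TGF-beta library, 4111 were at least 2-fold lower and 7899 lay between. Genes with 0 counts in a library were placed by their floor value. The 7899 can therefore hold genes whose difference is known only as a bound and may exceed 2-fold. Of the higher genes, 395 had 3 counts or fewer in both libraries, against 0 of the lower genes, and 2996 were left without them. Counting noise alone, simulated at this depth, put 1809 of 14671 unchanged genes past 2-fold higher and 1468 past 2-fold lower, so a large part of these counts needs no difference between the cells. At 20 CPM or more, 986 genes were higher and 1921 lower among 5341, against 162 and 128 of 4504 from simulated counting noise. Scatter from amplification did not enter the simulation, so the excess does not measure a difference between the cells. The balance also moved with scaling. Higher genes made up 45.2% of the calls with TMM and 34.1% (2463 higher and 4753 lower) with DESeq2 size factors. Part of that fall is the filter, as genes with 3 counts or fewer in both libraries no longer passed (14067 genes left). Without such genes TMM gave 2996 higher and 4111 lower. The scaling methods shifted every log2 ratio by -0.22 (DESeq2 size factors), -0.16 (total counts) or 0.08 (upper quartile) from the TMM values. Scaling on the ribosomal protein genes, chosen after seeing the data, shifted them by 3.58 and gave 14168 higher and 104 lower genes, 99.3% higher. Ratios are therefore relative to the bulk of the expressed genes, whose median log2 ratio was 0.01 with TMM.

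**Figure D2:**
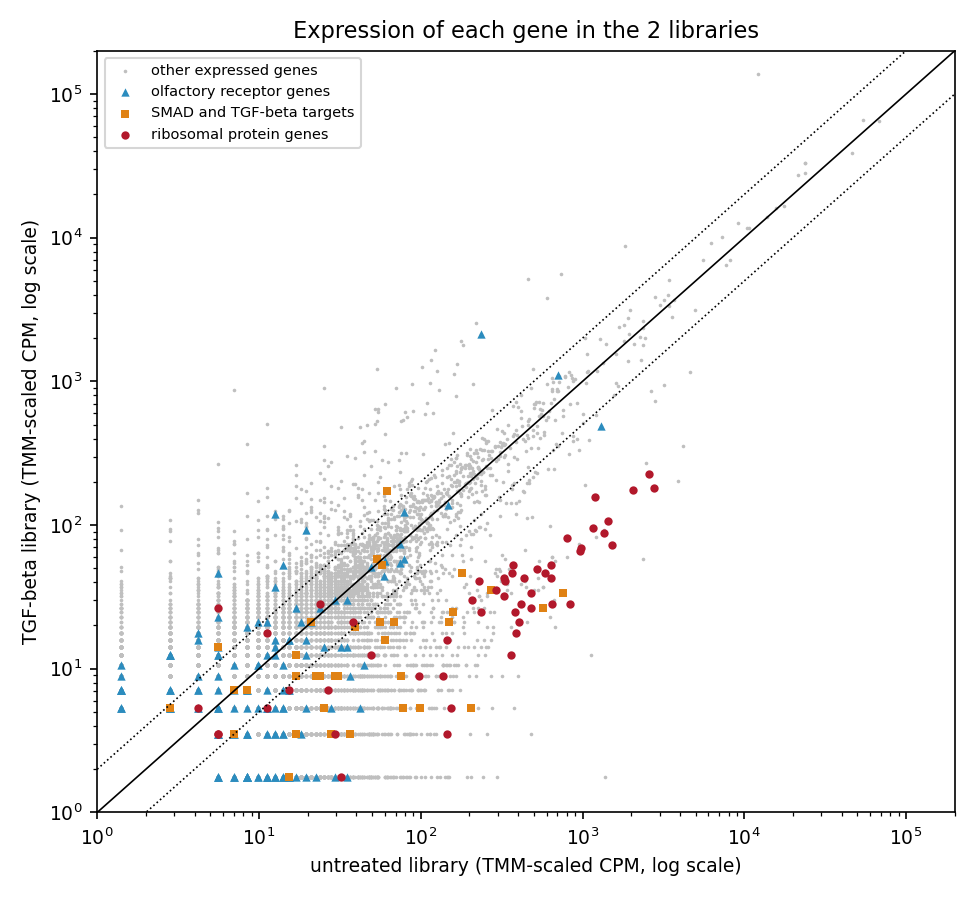
TMM-scaled CPM of 13493 expressed genes with at least 1 count in both libraries, untreated library on the horizontal and TGF-beta library on the vertical axis, both on log scales, with a solid line at equality and dotted lines at 2-fold. Ribosomal protein genes (red circles, 52 genes) lie mostly below the lines, SMAD and TGF-beta targets (orange squares, 34 genes) also lie mostly below them, and olfactory receptor genes (blue triangles, 152 genes, chosen after seeing the data) scatter on both sides.

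Genes of the immediate SMAD response and of TGF-beta feedback were lower in the TGF-beta library. Of 35 expressed members, 24 were at least 2-fold lower and 2 at least 2-fold higher, and the median log2 ratio was -1.80 (quartiles -3.03 and -0.68), at percentile 0.0 among the matched random lists. ANGPTL4, an inhibitor of lipoprotein lipase, had 3 counts against 146 with a log2 ratio of -5.27 (-7.56 to -3.69), and PMEPA1, a feedback inhibitor of TGF-beta signalling, had 3 against 71 with -4.23 (-6.54 to -2.62). The lists of collagen modifying enzymes (12 of 21 lower, 1 higher, median -1.25, percentile 0.52) and of matrix proteases and their inhibitors (13 of 27 lower, 5 higher, median -0.94, percentile 2.20) also stood apart below. Among these, TGM2, a crosslinking transglutaminase, had 1 count against 90 (log2 ratio -6.16, -11.48 to -3.64). TIMP1, a metalloproteinase inhibitor, had 0 against 35 and was 9.24-fold lower with the 0 set to the floor of 3 counts. The protease list no longer stood apart with total count scaling, with the 20 CPM filter or with genes counted over more than 1 exon. Ribosomal protein genes, at a median of -3.39, lay lower than all of these lists.

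The lists that describe the transition itself did not stand apart. Mesenchymal and EMT markers had a median log2 ratio of -0.28 (percentile 18.2), with 7 of 22 lower and 2 higher. S100A4, a calcium-binding protein of motile cells, had 9 counts against 193 (-4.09, -5.24 to -3.13). COL1A1, among the 2 higher members, had a log2 ratio of 1.20. EMT transcription factors had a median of 0.43 (percentile 87.9), with 3 of 14 lower and 3 higher. FOSL1, a subunit of AP-1, had 1 count against 145 (-6.84, -12.16 to -4.34), and TCF3 had 45 against 6 (3.24, 2.01 to 4.76). Epithelial junction and identity genes had a median of 0.34 (percentile 85.0), with 9 of 37 lower and 9 higher. Equal counts take this value after scaling. The protease inhibitor gene SPINT2 had 5 counts against 89 (-3.82, -5.48 to -2.54). Epithelial keratins had a median of 0.25 (percentile 67.9), with 3 of 10 lower and 4 higher, and KRT7 had 32 counts against 179 (-2.15, -2.74 to -1.60). With the 20 CPM filter the medians of the transcription factors, the junction genes and the keratins turned to -0.73, -0.86 and -0.84, and the keratin median was -0.06 with DESeq2 size factors.

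Other lists of matrix, adhesion and cytoskeleton were mixed. Integrins had a median log2 ratio of 0.63 (percentile 97.8), with 6 of 17 higher and 4 lower. ITGA4 had 50 counts against 23 (1.46, 0.72 to 2.24). The integrin list did not stand apart under 8 of the 12 other settings, and its median was 0.01 at 1 CPM. Collagens had a median of -0.00 (percentile 56.7), whose sign moved with scaling and filter, with 3 of 18 lower and 4 higher. COL6A2 had 21 counts against 4 (2.73, 1.16 to 4.73) and COL4A2 had 10 against 65 (-2.36, -3.49 to -1.39). Matrix glycoproteins had a median of 0.34 (percentile 88.8), with 10 of 30 lower and 6 higher, and the median turned to -0.86 with DESeq2 size factors, -0.43 at 1 CPM, -1.34 at 20 CPM and -0.64 with more than 3 counts in 1 library. Contractile and actin cytoskeleton genes had a median of -0.41 (percentile 10.4), with 13 of 29 lower and 4 higher, and stood apart below under 3 of the 12, with -1.69 at 20 CPM. TAGLN2 had 3 counts against 269 (-6.15, -8.44 to -4.59). YAP TEAD targets had a median of -1.08 (percentile 2.53), with 12 of 21 lower and 1 higher, and stood apart below under 8 of the 12 other settings. IGFBP3, an insulin-like growth factor carrier, had 5 counts against 227 (-5.17, -6.81 to -3.93).

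The ribosomal protein, heat shock, oxidative phosphorylation and glycolysis lists had the lowest medians of all lists with the main settings. With the 20 CPM filter the oxidative phosphorylation and glycolysis medians were -2.66 and -2.55, above those of the ATF4 (-2.90) and NRF2 (-2.83) lists. Of 53 expressed ribosomal protein genes, 46 were at least 2-fold lower in the TGF-beta library and 1 higher, with a median log2 ratio of -3.39 (quartiles -3.92 and -2.79, percentile 0.0). RPS12 had 16 counts against 600 (-4.89, -5.71 to -4.18). Together these genes held 0.219% of the TGF-beta library (exact 95% binomial interval 0.207% to 0.231%) and 2.93% of the untreated library (2.89% to 2.97%). Of 15 heat shock genes 13 were lower and 2 higher, with a median of -3.75 (percentile 0.0, and -3.11 at 1 CPM), and the mitochondrial chaperonin HSPD1 had 1 count against 107 (-6.41, -11.72 to -3.90). Oxidative phosphorylation genes (30 of 40 lower, 0 higher, median -2.25, percentile 0.0) and genes of glycolysis and hypoxia (26 of 38 lower, 4 higher, median -2.16, percentile 0.0) were also low. GAPDH, a glycolytic enzyme, had 115 counts against 2764 (-4.25, -4.53 to -3.98), and COX6B1, a subunit of cytochrome c oxidase, had 7 against 178 (-4.33, -5.67 to -3.26). Fatty acid genes had 14 of 26 members lower and 4 higher (median -1.21, percentile 0.28, with -0.55 at 1 CPM and -0.44, not apart, at 20 CPM), and the stearoyl-CoA desaturase gene SCD had 6 counts against 98 (-3.69, -5.17 to -2.52). Cholesterol synthesis genes did not stand apart (9 of 24 lower, 3 higher, median -0.36, percentile 17.0), and their median was -1.31 at 20 CPM.

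Stress and signalling lists lay low as well. NRF2 targets had 21 of 38 members lower and 4 higher, with a median log2 ratio of -1.75 (percentile 0.0). FTH1, the ferritin heavy chain, had 13 counts against 449 (-4.77, -5.69 to -3.99). The aldo-keto reductase gene AKR1C2 had 3 against 162 (-5.42, -7.71 to -3.85), although reads of this family can be divided between near-identical members. Unfolded protein response genes (10 of 19 lower, 2 higher, median -1.70, percentile 0.10, and -0.99 at 1 CPM) included calreticulin, CALR, with 22 counts against 299 (-3.43, -4.12 to -2.80). Genes of the ATF4 response (16 of 29 lower, 2 higher, median -1.23, percentile 0.04) included ATF4 itself with 6 against 158 (-4.38, -5.85 to -3.23). Immediate early genes (17 of 31 lower, 6 higher, median -1.14, percentile 0.42, not apart by the mean or over more than 1 exon) included the phosphatase gene DUSP1 with 9 against 106 (-3.22, -4.39 to -2.24). NF-kappaB and cytokine genes (15 of 29 lower, 4 higher, median -1.08, percentile 0.64) included IL8, the neutrophil chemokine interleukin 8, with 0 counts against 193. IL8 was 51.0-fold lower with the 0 set to the floor of 3 counts. In the same list ICAM1 had a log2 ratio of 3.62, and the list's summed count was 1073 in each library. Cyclin dependent kinase inhibitors and p53 targets (14 of 26 lower, 4 higher, median -1.20, percentile 0.16, not apart with the 20 CPM filter) included CDKN1A with 14 counts against 113 (-2.68, -3.59 to -1.87). With the 20 CPM filter the medians of the NRF2, ATF4 and NF-kappaB lists were -2.83, -2.90 and -1.99, and the ATF4 median was -1.82 with log2(CPM + 1). Ribosomal protein genes moved in the same direction by a median of -3.39 beside each of these lists.

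The cell cycle lists did not stand apart. Genes of G1/S and DNA replication had a median log2 ratio of -0.63 (percentile 6.48, and -0.02 at 1 or 20 CPM), with 11 of 27 lower and 5 higher, and genes of G2/M and mitosis had a median of -0.31 (percentile 9.04), with 6 of 28 lower and 6 higher, a median that turned to 0.60 with the 20 CPM filter. PCNA, the sliding clamp of DNA replication, had 1 count against 22 (-4.12, -9.49 to -1.49), and NUSAP1, a spindle protein, had 32 against 2 (4.34, 2.37 to 7.44). Wnt pathway genes had the highest median, 0.64 (percentile 99.6), with 12 of 34 higher and 4 lower. ZNRF3, a ubiquitin ligase that removes Wnt receptors, had 2934 counts against 329 (3.49, 3.33 to 3.66), with only 0.276% of them outside its main exon. The Wnt list no longer stood apart with the 20 CPM filter. BMP and ID targets (5 of 12 higher, 3 lower, median 0.52, percentile 81.4), Notch pathway genes (4 of 15 higher, 3 lower, median -0.04, percentile 54.5) and receptor tyrosine kinases with their ligands (9 of 22 lower, 3 higher, median -0.20, percentile 33.5, and 0.20 at 20 CPM) did not stand apart. INSR, the insulin receptor gene, had 89 counts against 8 (3.81, 2.77 to 5.07).

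Lung, immune and other lineage genes were near the bulk of the genes or too sparse to rank firmly. Lung alveolar and airway genes (median 0.25, percentile 67.7), acute phase genes (0.34, percentile 71.7), interferon response genes (0.34, percentile 76.5) and drug transporter and stemness genes (0.45, percentile 78.5) did not stand apart, and neither did antigen presentation genes (7 of 13 lower, 3 higher, median -1.25, percentile 3.78). The acute phase median turned to -0.54 with DESeq2 size factors and to -0.33 with more than 3 counts in 1 library. The medians of the lung list (-0.12) and of the fibroblast list (-0.21) also turned with DESeq2 size factors, under which genes at the floor no longer passed the filter. With more than 3 counts in 1 library and TMM these 2 medians were 0.10 and 0.01. B2M, the light chain of MHC class I, had 3 counts against 46 (-3.60, -5.93 to -1.97). Markers of fibroblasts (median 0.12, percentile 57.1), endothelium (-0.24, percentile 37.3) and leukocytes (-1.19, percentile 5.50) did not stand apart. At 20 CPM the fibroblast median was 0.71 and the leukocyte median -2.75, against -0.25 for leukocytes at 1 CPM. Melanocyte and neural markers did, at -1.36 (percentile 2.33, 6 of 10 lower, 2 higher). PMEL, a melanosome protein, had 1 count against 20 (-3.99, -9.36 to -1.34), and the call was lost with total counts, the 20 CPM filter, the list mean, and genes counted over more than 1 exon. COL1A1, a fibroblast marker here and also in the mesenchymal and collagen lists, had 356 counts against 196 (1.20, 0.94 to 1.46).

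**Figure D3:**
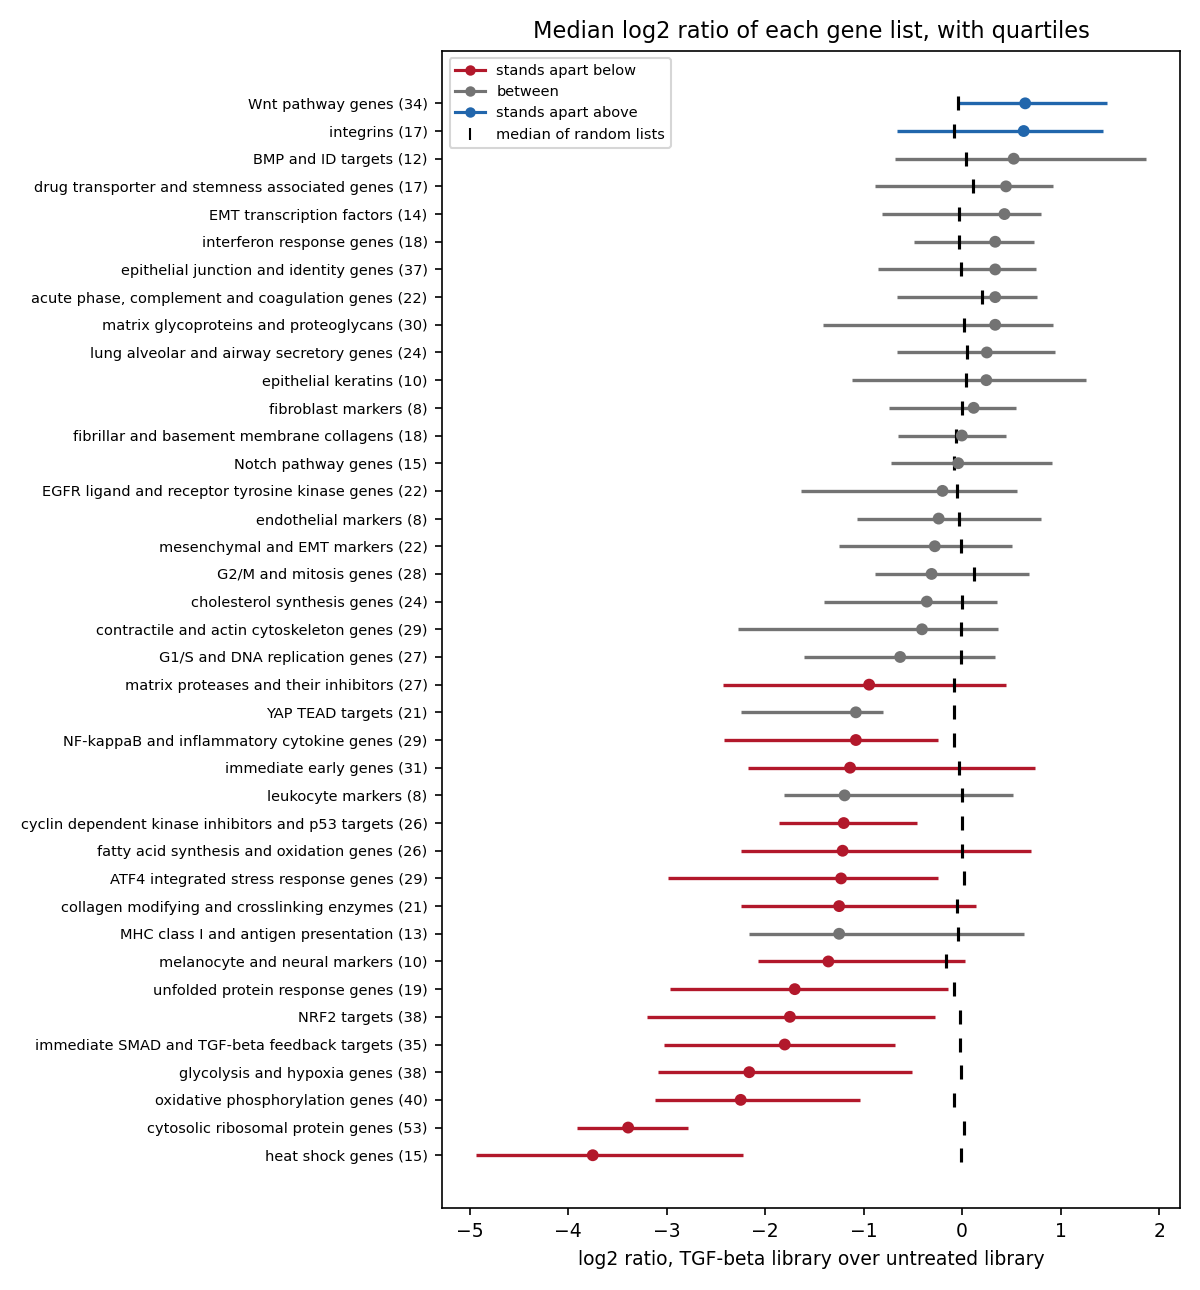
Median log2 ratio of the TGF-beta library over the untreated library for each of the 39 gene lists (points), with the quartiles of the members (lines), the median of 10000 matched random lists (ticks) and the number of expressed members in brackets. There are 15 lists that stand apart below (red) and 2 above (blue), and the remaining lists (grey) lie between.

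Among genes with at least 20 CPM in 1 library, MFN1, a mitochondrial fusion gene, had the smallest ratio, with 1 count against 977 (-9.60, -14.90 to -7.12), all in 1 exon. PSAP, which encodes the precursor of the saposins, had 1 against 210 (-7.38, -12.69 to -4.88). TUBA1C, an alpha-tubulin with close paralogs, had 2 against 343 (-7.09, -10.14 to -5.22). PABPC1, the cytoplasmic poly(A)-binding protein, had 7 against 802 (-6.50, -7.82 to -5.45). The genes with the largest ratios included C2CD5 with 494 counts against 5 (6.96, 5.73 to 8.59), CHIT1, a chitinase gene of macrophages, with 286 against 8 (5.50, 4.50 to 6.72), and ADCY1, an adenylate cyclase gene, with 509 against 18 (5.16, 4.48 to 5.92). In these 3 genes 0.401%, 1.84% and 4.02% of the counts lay outside the main exon, against 36.0% for PSAP and 38.5% for PABPC1.

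Of the 10 genes with the most counts in each library, 9 were common to both. CTD-2587M23.1, a gene with a single exon on chromosome 5 (1725264 to 1728287, plus strand), held 13.0% of the TGF-beta library and 1.29% of the untreated library (77313 against 8670 counts, log2 ratio 3.49, 3.46 to 3.52). IFFO1 held 6.13% and 7.22%, MPDU1 6.23% and 5.76%, and TARBP1 3.71% and 4.94%, each with under 1% of the counts outside the main exon. ZCCHC17 and RP11-266K22.2 overlap on opposite strands of chromosome 1 and had nearly equal values (18745 and 18747 counts in the TGF-beta library), so that neither level can be assigned to 1 gene.

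**Figure D4:**
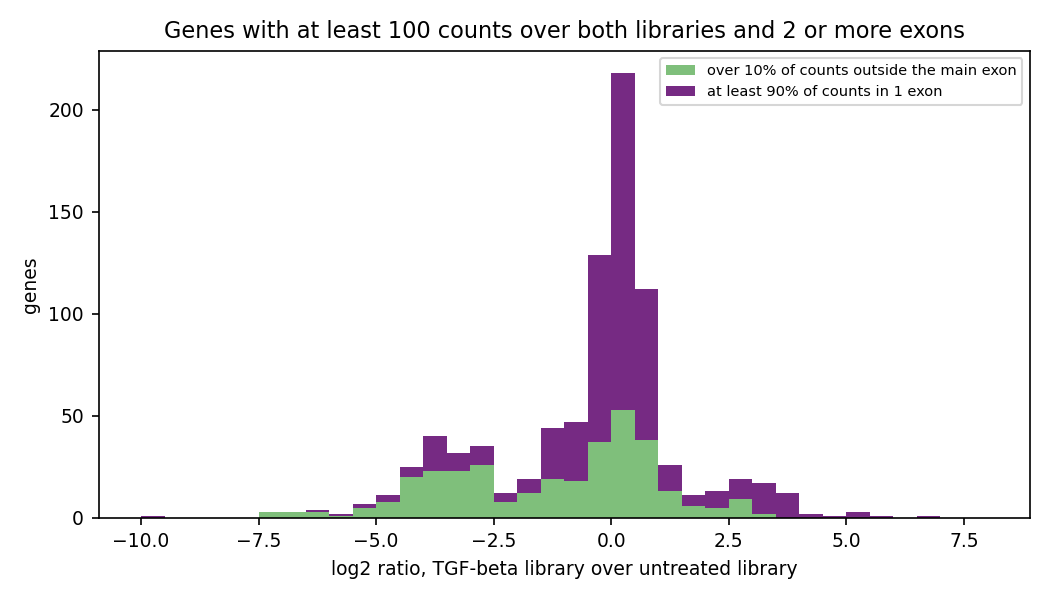
Number of genes by log2 ratio of the TGF-beta library over the untreated library, for 850 genes with at least 100 counts over both libraries and 2 or more exons, split into 515 genes with at least 90% of their counts in 1 exon (purple) and 335 others (green). With both libraries pooled, at least 90% of counts in 1 exon was seen in 76.8% of the genes at log2 ratios of 2 or more. The share was 48.6% from 1 to 2, 71.1% between -1 and 1, 50.8% from -2 to -1, and 29.7% at -2 or less.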

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

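The scalings on ribosomal protein genes and without the top genes, and the restrictions by exon and to more than 3 counts in 1 library, were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Against 3391 genes higher and 4111 lower, the counts were 6903 and 7430 at 1 CPM or with no filter (27275 genes), 986 and 1921 at 20 CPM (5341 genes), 1153 and 1927 at 4-fold, 651 and 1623 with the counting interval beyond 1.5-fold, and 5117 higher at 1.5-fold. These differences follow from how many genes or which sizes each rule admits. Scaling on ribosomal protein genes gave 14168 and 104, because it shifts every ratio by 3.58. Genes with at least 10% of their counts outside the main exon (9927 genes) gave 2034 higher, and genes with more than 3 counts in 1 library (14067 genes) gave 2996. The other settings stayed within 1.5 times. The number of lists standing apart was 17 and ranged from 13 to 19 over 12 settings, and 12 to 17 of the same lists stood apart in each. Of 312 list medians under planned settings 31 moved beyond the counting spread and 281 did not, and of 1079 ratios of named genes 1 did (ZNRF3, 3.27 with DESeq2 size factors). The 20 CPM filter moved 14 medians and DESeq2 size factors 11, with 5341 and 14067 genes past the filter. Depth limits the result too: only 1965 genes had at least 20 counts in the TGF-beta library.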

Other observations

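All tests in this part, and the gene families in it, were chosen after the values had been seen. Several further families were lower in the TGF-beta library. Canonical histone genes, which package new DNA, had 37 of 55 expressed members at least 2-fold lower and 7 higher, with a median log2 ratio of -1.99 (percentile 0.0 among 10000 matched random lists), and HIST1H4C had 20 counts against 357 (-3.82, -4.55 to -3.17). S100 genes, which encode calcium-binding proteins, had 7 of 9 members lower and 0 higher (median -3.36, percentile 0.02). Tubulin genes had 8 of 13 lower and 2 higher (-2.25, percentile 0.02). Proteasome subunit genes had 27 of 34 lower and 1 higher (-2.40, percentile 0.0), although PSMD3 had 260 counts against 276 (0.25, -0.00 to 0.50). Translation initiation and elongation factor genes had 42 of 79 lower and 11 higher (-1.25, percentile 0.0), with EEF2 at 21 against 405 (-3.93, -4.64 to -3.30) and EEF1D at 759 against 961 (-0.00, -0.14 to 0.13). Annexin genes did not stand apart as a family (3 of 7 lower, 2 higher, -0.45, percentile 23.9), while ANXA2 had 19 against 259 (-3.43, -4.19 to -2.76). Of 4 expressed metallothionein genes, too few to rank, 2 were lower. MT2A had 42 counts against 682 (-3.69, -4.17 to -3.24) and MT1X 1 against 31 (-4.62, -9.97 to -2.03), while MT1F had 5 against 1 (2.66, -0.50 to 8.22) and MT1E had 3 against 1, which gave no ratio.

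Zinc finger, solute carrier and protocadherin families did not stand apart. Zinc finger genes named ZNF had a median of 0.16 (percentile 89.8, 67 of 274 higher and 57 lower), solute carrier genes 0.22 (percentile 97.2, 58 of 231 higher and 54 lower) and protocadherin genes 0.12 (percentile 66.1, 10 of 46 higher and 10 lower). Olfactory receptor genes, which encode odorant receptors of sensory neurons, held 0.564% of the TGF-beta library (exact 95% binomial interval 0.545% to 0.583%) and 0.555% of the untreated library (0.537% to 0.573%), over 401 genes. They stood apart below, with 83 of 213 expressed members lower, 38 higher and a median of -0.41 (percentile 0.0). Their summed log2 ratio was 0.18 (0.12 to 0.25), and it turned to -0.39 (-0.46 to -0.31; 2167 against 3575 counts) without OR4Q3, which had 1199 counts against 167. In the TGF-beta library they held more counts than the ribosomal protein genes, 3366 against 1306, and in the untreated library fewer, 3742 against 19738.

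Ribosomal protein genes were lower in the TGF-beta library, as were several other lists and families. With the 20 genes with the most counts left out of the totals, every log2 ratio shifted by 0.17 and the ribosomal median was -3.22. The weight of these genes in the totals therefore does not account for the pattern as a whole. Any effect of these genes during amplification was not tested. A candidate explanation is that less of the TGF-beta library derived from mRNA: of 9 other lists with at least 10 members of 50 or more counts, 88.9% had a median at or below -1, the exception being mesenchymal and EMT markers at -0.28. Most of these lists already had a main median at or below -1, so this share restates the pattern and does not test its cause. An effect of TGF-beta on these genes was not tested and stays open, as 1 library per condition cannot separate it from the quality of that library.

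TGF-beta targets such as TGFBI were lower in the library labelled TGF-beta, the opposite of the textbook response. Among genes with 50 or more counts, the median log2 ratio of 16 targets was -2.74, at percentile 8.26 among 10000 random lists drawn from 185 members of the other lists, ribosomal protein genes left out, and matched on summed count. Medians of such random lists ran from -3.19 to -0.06 (central 95%), so exchanged labels and a smaller mRNA-derived share of the TGF-beta library cannot be told apart by these genes. Relative to the median of 39 ribosomal protein genes with 50 or more counts (-3.67), TGFBI was -0.76 (-1.61 to -0.02) and VIM 0.99 (0.57 to 1.40). These intervals leave out the spread of the ribosomal protein genes (quartiles -3.95 and -3.28). Among those genes TGFBI lay at percentile 15.4 and VIM at percentile 97.4. TGFBI was therefore not set apart from them, and VIM lay near their upper end. Whether the cells answered TGF-beta was not tested and stays open.

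Of 954 genes with 100 or more counts, 205 were at least 4-fold lower in the TGF-beta library, 550 lay within 2-fold and 85 were at least 4-fold higher. Products confined to 1 exon, as genomic DNA or priming off target would give, are a candidate explanation: among genes with 2 or more exons, 53 of 69 higher genes had 90% of their counts in 1 exon against 52 of 175 lower genes (odds ratio 7.76, exact 95% interval 3.95 to 16). A designed amplicon can also lie within 1 exon, and 71.1% of the genes within 2-fold had this form, so it does not single out the higher genes. The share was 48.6% for genes 2- to 4-fold higher and 50.8% for genes 2- to 4-fold lower. Exon shares pooled both libraries. Counts came mostly from the TGF-beta library in the 85 higher genes (116042 against 14862) and from the untreated library in the 205 lower genes (67074 against 4767). The odds ratio therefore cannot tell gene groups from libraries apart, and its interval treats genes as independent. Expression induced by TGF-beta in these genes was not tested and stays open.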
